A study of Caenorhabditis elegans with 12 samples.

How the data were processed

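RNA recovered with antibodies against FLAG or MYC was sequenced from whole young adult Caenorhabditis elegans of 3 transgenic strains, which carried a FLAG-tagged copy of the Y-box protein CEY-1, CEY-2 or CEY-4. The strains are called CEY1, CEY2 and CEY4 here. The FLAG immunoprecipitations (IPs) were meant to bring down the tagged protein with its mRNAs, and the MYC IPs from the same strains served as controls. Each of the 6 groups of strain and antibody held 2 libraries, 12 in all. Per the labels, RNA was taken from the beads with Trizol and made into libraries with the ScriptSeq v2 kit. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries.

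The deposited raw table holds counts per gene, one column per library, for 20182 genes. The aligner, genome build, annotation and counting program are not given in the sources used here, and how reads shared by near-identical genes were counted is unknown. The deposited normalized table holds log2 values: the authors scaled the raw counts of every library to one common total and added 8 before taking the logarithm, which was checked by recovering the raw counts from it. Gene symbols were matched by identifier, and 18778 of the 20182 identifiers (93.0%) had one. The table holds none of the mitochondrially encoded genes, ribosomal RNAs or spliced leader RNAs of the lists written beforehand.

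Total counts per library ran from 22915137 to 33529549 for the FLAG IPs and from 3353523 to 12802412 for the MYC IPs. At the smallest total, 1 CPM before TMM scaling corresponds to about 3.35 counts. PCR reads without molecular identifiers are not independent molecules, so statements on depth cover counting error only.

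Raw counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group at its default minimum count of 10, which left 15194 genes, 14427 of them with a symbol. Libraries were scaled by the trimmed mean of M values (TMM), whose factors lay between 0.548 and 0.640 for the FLAG libraries and between 1.51 and 2.13 for the MYC libraries. One mean per group was fitted over all 12 libraries, so that the 6 groups shared the estimate of the spread (common biological coefficient of variation 0.0476). Quasi-likelihood F tests compared FLAG with MYC IPs in each strain, the log2 enrichments of FLAG over MYC between strains (an interaction contrast), and the MYC IPs of the strains with each other. A further model with strain and antibody as terms compared the 6 FLAG with the 6 MYC libraries. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with the standard error derived from the F statistic, CPM values are TMM-scaled, and SD is over the 2 libraries of a group. The log2 fold changes are relative within libraries: no spike-in or input fixes how much RNA each IP recovered.

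Before the data were examined, lists of C. elegans genes were written from textbook knowledge, and 19 of them had at least 3 tested members. They cover ribosomal proteins, translation factors, proteasome subunits, the respiratory chain, oocyte and maternal mRNAs, germline RNA-binding and P-granule proteins, reported targets of the translational repressor GLD-1, meiosis, the cell cycle, sperm, major sperm proteins, histones, intestine, body wall muscle, pharynx, cuticle collagens, neurons, somatic gonad and stress. Of the 16 GLD-1 targets, 12 also stand in the oocyte list. Lists were tested with the camera test of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation preset at 0.01), adjusted over the 19 lists and the 6 enrichment comparisons. The MYC IPs were compared by list in a separate family of 3 comparisons. Camera asks whether a list ranks above or below the other genes, so a call does not depend on the sign of its median. Medians in which a member at 0 in both libraries of a group is set to 3 counts over that group were also computed: of the medians given, the largest moves were then from −0.45 to −0.36 (intestine, CEY2 relative to CEY4 in the MYC IPs) and from −0.76 to −0.83 (intestine with CEY2). No medians are given for the major sperm proteins, of which up to 3 of 10 were at 0 in a FLAG group.

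The rule for naming genes was also fixed before the data were examined. For FLAG against MYC in each strain it took the 8 largest log2 fold changes in each direction among called genes with a mean of at least 10 CPM in the higher group, with every FLAG library on one side of every MYC library, and with a standard symbol. Histones, major sperm proteins and other near-identical copies were left out of that ranking. For the differences of enrichment it took 4 in each direction, without asking for separation of the libraries. All genes of the Y-box list (the cey genes, lin-28, and parts of the transgenes) and up to 4 members of each list with the lowest adjusted p were added.

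Alternatives chosen before the data were examined were size factors by the median of ratios (RLE), no filter beyond 1 count, a filter at 10 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, the replicate number as a block, only the libraries of the groups compared, each library left out in turn, and limma-trend on the deposited log2 values. For the lists they were camera with an estimated correlation and fry, a rotation test of the list's own genes. Scaling on mitochondrially encoded mRNAs was planned but not run, because the table holds none. Added after the data were seen were total-count scaling, FLAG libraries thinned to the depth of the MYC libraries, FLAG libraries compared directly without controls, and the pharynx list without its pqn, abu and phat families.

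The procedure was tested on simulated data. Of simulated genes with a 2-fold change, 65 of 67 were called, and 50 of 67 with a 1.5-fold change, with 10 false calls among 14322 genes. Of 5 lists of 30 genes raised 2-fold, 5 were called, with 0 calls among 15 unchanged lists. Only a small share of the simulated genes changed, in the CEY1 FLAG group alone, and genes were drawn independently of each other. The simulation therefore does not test the scaling where most genes differ, as in the real data. Nor does it test the effect of correlation within a list.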

Results

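Y-box proteins are RNA-binding proteins with a cold-shock domain that associate with mRNAs in the cytoplasm. The mRNAs that came down with FLAG-tagged CEY-1, CEY-2 or CEY-4 were compared with those in control MYC IPs from the same strains of young adult worms. Each strain gave 2 FLAG and 2 MYC libraries. The CEY1 FLAG libraries held 28600967 and 22915137 counts, those of CEY2 28940989 and 33529549, and those of CEY4 29903497 and 29481913. The MYC libraries were shallower, with 4713239 and 6666476 counts for CEY1, 3605114 and 3353523 for CEY2, and 12802412 and 11651770 for CEY4. Fewer genes reached 1 CPM (before TMM scaling) in the FLAG libraries, between 8947 and 9136, against 12386 to 13368 in the MYC libraries. In the deeper FLAG libraries 1 CPM is a larger count, so this does not measure detection. Genes with at least 1 count ranged from 15118 to 15944 in FLAG and from 15496 to 17822 in MYC libraries. Replicates correlated with r between 0.993 and 0.994 (FLAG) and between 0.970 and 0.982 (MYC) across genes, which are not independent replicates.

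Each FLAG IP recovered the mRNA of its own tagged protein. The cey-1 mRNA (WBGene00000472) stood at 2685 ± 178 CPM (SD, n = 2) in the CEY1 FLAG IP and 266 ± 9.35 CPM in its MYC control. Its log2 fold change was 3.34 ± 0.06 (SE, adjusted p = 1.36e-36 by edgeR), against 1.42 ± 0.06 with CEY2 and 1.92 ± 0.06 with CEY4. The cey-2 mRNA (WBGene00000473) stood at 3026 ± 62.03 CPM in the CEY2 FLAG IP and 374 ± 23.7 CPM in its control (3.02 ± 0.06, adjusted p = 9.85e-36). It was lower with CEY1 (−1.61 ± 0.06) and little changed with CEY4 (0.25 ± 0.05, adjusted p = 8.63e-05). The cey-4 mRNA (WBGene00000475) stood at 5993 ± 37.2 CPM in the CEY4 FLAG IP and 680 ± 8.37 CPM in its control (3.14 ± 0.05, adjusted p = 6.33e-37), against 0.72 ± 0.05 with CEY1 and 0.84 ± 0.05 with CEY2. These 3 values ranked 181 (cey-1), 345 (cey-2) and 47 (cey-4) among the enrichments of 15194 genes. With total-count scaling the own values stayed positive, but cey-1 with CEY2, cey-2 with CEY4, and cey-4 with CEY1 and CEY2 turned negative.

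**Figure D1:**
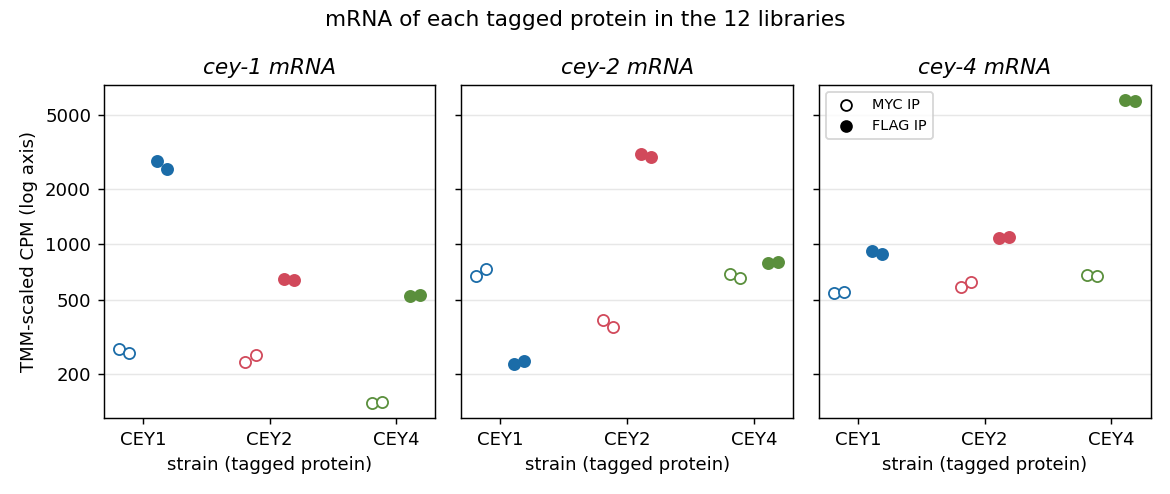
TMM-scaled CPM (log axis) of the cey-1, cey-2 and cey-4 mRNAs in every library, by strain. Each point is 1 library, open for MYC and filled for FLAG IPs, and a strain's colour is the same in each panel. Each mRNA is highest in the FLAG IP of the strain that carries its tagged protein, with means of 2685, 3026 and 5993 CPM.

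The mRNA of cey-3, whose protein was not tagged, had log2 fold changes of −0.15 ± 0.06 with CEY1 (adjusted p = 0.0239), 1.05 ± 0.06 with CEY2 and −0.07 ± 0.06 with CEY4 (adjusted p = 0.264). The CEY1 value missed the threshold without CEY1 FLAG replicate 1 (−0.07) or CEY1 MYC replicate 1 (−0.12). For lin-28, a cold-shock-domain regulator of developmental timing, the values were 0.65 ± 0.13, 1.18 ± 0.13 and 0.23 ± 0.12 (adjusted p = 0.0725 with CEY4), and the last passed the threshold when CEY4 MYC replicate 1 was left out (0.46). The beta-tubulin gene tbb-2, whose 3' UTR is part of the transgenes, had 1.71 ± 0.05, 1.11 ± 0.05 and 0.34 ± 0.05, and reads from the transgene cannot be separated from its own. The marker gene unc-119 lay near the floor, at 0.593 to 3.44 CPM, with values of 0.65 ± 0.33 (adjusted p = 0.0768), 0.53 ± 0.36 (adjusted p = 0.189) and −1.78 ± 0.38. Without CEY1 MYC replicate 1 the first passed the threshold (1.01). For dpy-30 the values were −0.66 ± 0.17, 0.95 ± 0.16 and −0.22 ± 0.14 (adjusted p = 0.162), and the first missed the threshold without CEY1 MYC replicate 1 (−0.17). With total-count scaling the positive values of cey-3, lin-28, unc-119 and dpy-30 turned negative, as did those of tbb-2 with CEY2 and CEY4.

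The mRNAs most enriched in the CEY1 FLAG IP included those of glutamine-rich proteins and of the RNA-binding proteins GLA-3, NOS-3 and DAZ-1. The largest enrichment was that of pqn-20 (WBGene00004110), which encodes a prion-like glutamine- and asparagine-rich protein, at 11459 ± 215 CPM against 330 ± 75.6 CPM (log2 fold change 5.13 ± 0.08). It was followed by sel-8, a coactivator of Notch signalling (4.43 ± 0.07), gla-3, which encodes a zinc-finger RNA-binding protein of the germline (4.34 ± 0.08), and nos-3, a Nanos homolog (4.20 ± 0.07). The glutamine-rich pqn-41 (4.15 ± 0.08), abu-11 (4.15 ± 0.23), the DAZ homolog daz-1 (4.10 ± 0.07) and the kinase pak-2 (4.08 ± 0.08) completed the set. Lowest were the glutathione S-transferase gst-4 (−4.79 ± 0.31, 0.426 against 11.9 CPM), dct-11 (−4.56 ± 0.21), the transthyretin-like ttr-51 (−4.27 ± 0.27) and the ribosomal protein gene rpl-36.A (−4.24 ± 0.08, 33.8 against 643 CPM). The nuclear receptor nhr-210 (−4.21 ± 0.28), the sideroflexin sfxn-5 (−4.16 ± 0.18), nspg-6 (−4.04 ± 0.29) and the saposin-like spp-17 (−4.03 ± 0.13) were also among them. All 16 were called, with adjusted p from 1.64e-37 (pqn-20) to 8.03e-16 (nspg-6). In total 4910 genes were higher and 5223 lower with the FLAG antibody. Total-count scaling moved the median of all genes by −1.49 and gave 1647 higher and 10849 lower, so the balance of directions depends on the scale.

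By gene group, 29 of 34 germline RNA-binding and P-granule genes were higher with CEY1 and 1 was lower (30 and 2 adjusted over the list alone, median 1.93, and 0.44 with total-count scaling). Examples are sqd-1 (3.35 ± 0.05) and atx-2 (3.65 ± 0.06). Limma's camera gave adjusted p = 5.4e-13, and adjusted p = 0.102 with an estimated correlation. Of 37 oocyte and maternal mRNAs, 31 were higher and 5 lower (the same counts adjusted over the list alone), among them the zinc-finger genes mex-5 (3.75 ± 0.07) and mex-1 (3.64 ± 0.07), and cpg-1, which encodes a chondroitin proteoglycan of the eggshell (2.99 ± 0.05). Their median was 1.18, but −0.31 with total-count scaling (adjusted p = 1.53e-08, and adjusted p = 0.0999 with an estimated correlation). The GLD-1 targets (14 higher, 2 lower of 16, median 1.15, but −0.34 with total-count scaling) include the Notch receptor glp-1 (2.49 ± 0.05) and had adjusted p = 6.33e-05, or adjusted p = 0.0999 with an estimated correlation. Cell cycle genes such as icp-1 (3.63 ± 0.06) were 23 higher and 4 lower of 29 (median 1.11, but −0.38 with total-count scaling, adjusted p = 1.39e-06, and adjusted p = 0.0959 with an estimated correlation). Meiosis genes were 22 higher and 4 lower of 28 (median 0.88, but −0.61 with total-count scaling, adjusted p = 0.000296, and adjusted p = 0.0707 with an estimated correlation). For these 3 lists the counts adjusted over the list alone were the same.

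The pharynx and body wall muscle lists were also called with CEY1. Of 74 pharynx genes 56 were higher and 7 lower (57 and 7 adjusted over the list alone, median 1.99, and 0.50 with total-count scaling), mostly members of the pqn, abu and phat families such as pqn-65 (3.68 ± 0.07) and pqn-87 (2.78 ± 0.06). Camera gave adjusted p = 4.67e-09, and adjusted p = 0.0505 with an estimated correlation. Reads shared by these related genes could not be told apart from the table. The pqn genes are named for a glutamine- and asparagine-rich sequence and not for a tissue, so the full list does not stand for the pharynx. Without these 3 families 9 genes remain. Of them 8 were higher and 1 lower with CEY1 (median 1.65), 1 and 6 with CEY2 (−0.45), and 6 and 2 with CEY4 (1.77). Of 35 body wall muscle genes 28 were higher and 2 lower (the same adjusted over the list alone, median 0.91, but −0.58 with total-count scaling), with the calponin-like clik-1 at 2.50 ± 0.05, the actin act-4 at 2.44 ± 0.05 and the paramyosin unc-15 at 2.17 ± 0.05. Their adjusted p was 8.45e-07, and adjusted p = 0.111 with an estimated correlation. In the intestine list the vitellogenins vit-2 (2.69 ± 0.05, 31612 against 4903 CPM) and vit-6 (2.14 ± 0.04) were higher and the lysozyme lys-4 lower (−3.39 ± 0.10). The list as a whole had 19 higher and 12 lower of 36 (19 and 13 adjusted over the list alone, adjusted p = 0.11). Lower groups were the histones, with 14 of 16 lower and 1 higher (the same adjusted over the list alone, median −1.54, his-61 −2.88 ± 0.08, adjusted p = 1.46e-06, and adjusted p = 0.141 with an estimated correlation), and the cuticle collagens. Of 157 collagen and hypodermis genes 74 were lower and 27 higher (the same adjusted over the list alone, median −0.85, adjusted p = 0.000249, and adjusted p = 0.282 with an estimated correlation), with col-101 at −2.01 ± 0.07 but the adult collagen col-19 at 2.04 ± 0.06. With total-count scaling the histone and collagen medians were −3.03 and −2.34.

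Ribosomal protein mRNAs split with CEY1 instead of moving together. Of 79 genes 34 were higher and 42 lower (the same adjusted over the list alone), with rps-0 at 14874 ± 1126 against 1283 ± 174 CPM (3.54 ± 0.06), rpl-11.2 at 3.23 ± 0.06 and rps-1 at 3.09 ± 0.06, but rps-19 at 73.4 ± 0.108 against 703 ± 59.8 CPM (−3.26 ± 0.07). The list's adjusted p was 0.335. The SD of the log2 fold changes over these 79 genes was 1.87 with CEY1, 0.859 with CEY2 and 1.26 with CEY4, against 1.33, 1.51 and 1.19 over the 1434 genes at 100 CPM or more in the controls. Other lists were not called with CEY1: translation factors (16 higher and 17 lower of 34, with pab-1 at 2.86 ± 0.05, adjusted p = 0.955, median −0.16, mean 0.05), proteasome subunits (12 and 16 of 33, adjusted p = 0.453), sperm genes (6 and 19 of 36, adjusted p = 0.101) and major sperm proteins (0 and 7 of 10, adjusted p = 0.118). The same held for neurons (38 and 23 of 113, with the endocytic ehs-1 at 3.36 ± 0.07, adjusted p = 0.806, median 0.17, mean −0.02), somatic gonad (6 and 6 of 14, adjusted p = 0.68) and stress genes (9 and 8 of 21, adjusted p = 0.737, the median was −0.39 while camera ranked the list up). The respiratory chain stood at the threshold (14 higher and 26 lower of 45, adjusted p = 0.0501) and was called, as lower, without CEY1 FLAG replicate 1 (0.0439) or 2 (0.0434), CEY2 FLAG replicate 1 (0.0492) or 2 (0.0499), CEY1 MYC replicate 2 (0.0299) or CEY4 MYC replicate 2 (0.0491). Adjusted over the list alone, the counts of these 8 lists differed by at most 2.

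**Figure D2:**
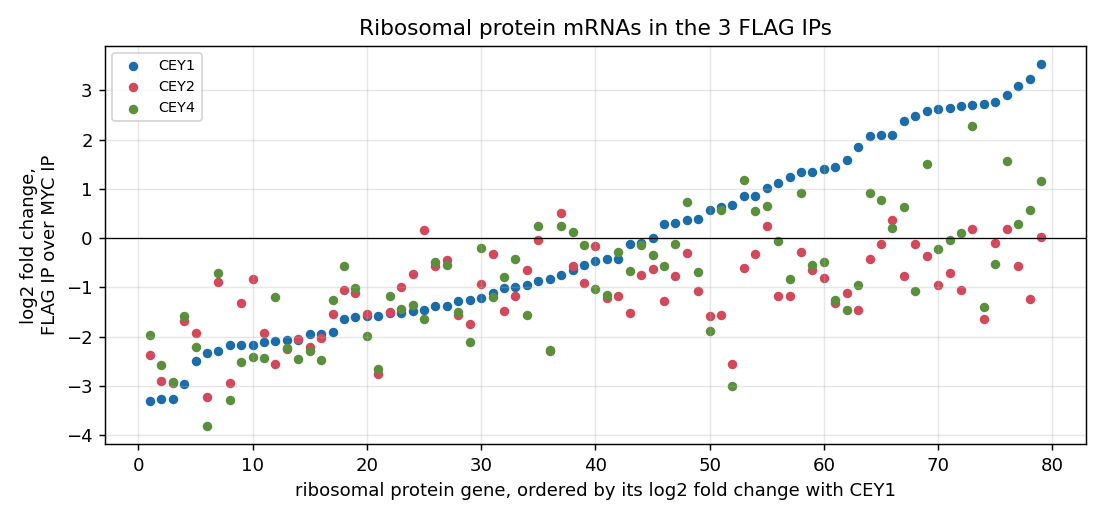
Log2 fold change of FLAG over MYC IP for each of the 79 ribosomal protein genes in the 3 strains, ordered along the x axis by the value with CEY1. Each point is 1 gene in 1 strain. With CEY1 34 genes were called higher and 42 lower, and with CEY2 5 higher and 66 lower; with total-count scaling these counts were 17 and 58 with CEY1, and 0 and 79 with CEY2.

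The CEY2 FLAG IP recovered nearly all mRNAs of the oocyte, meiosis and cell cycle lists. The largest changes were again pqn-20 (4.49 ± 0.08), then the polo kinase plk-3 (4.45 ± 0.09), arid-1 (4.19 ± 0.08), pdzd-8 (4.09 ± 0.07), the SET-domain gene set-9 (4.05 ± 0.07), pqe-1 (3.92 ± 0.06), sumv-1 (3.86 ± 0.08) and the APC-related apr-1 (3.85 ± 0.07). Lowest were the chromodomain gene cec-8 (−4.43 ± 0.11, 10.2 against 220 CPM), nhr-210 (−3.52 ± 0.27), the glucuronosyltransferase ugt-29 (−3.49 ± 0.12), rpl-39 (−3.23 ± 0.09), math-3 (−3.16 ± 0.18), the nitrilase nit-1 (−3.13 ± 0.26), the chemoreceptor srw-85 (−3.07 ± 0.26) and the prolyl hydroxylase phy-2 (−3.03 ± 0.13). All 16 were called, with adjusted p from 1.07e-37 (pqe-1) to 1.07e-13 (srw-85). Except for nhr-210 and math-3, the lowest genes were also higher in the CEY2 controls than in the other controls. For example, cec-8 stood at 220 CPM in CEY2 controls, against 26.1 (CEY1) and 70.7 (CEY4), and phy-2 at 93.8 against 10.9 and 10.3. Among the FLAG IPs, phy-2 was highest with CEY2 (11.4 CPM, against 6.17 with CEY1 and 3.73 with CEY4). In total 5300 genes were higher and 5177 lower. With total-count scaling, which moved the median by −1.71, these were 2013 and 10892.

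All 28 meiosis genes, all 29 cell cycle genes and all 16 GLD-1 targets were called higher with CEY2, as were 35 of 37 oocyte genes (2 lower) and 33 of 34 germline RNA-binding genes (0 lower), and each count was the same adjusted over the list alone. The oocyte median was 2.59 and 0.86 with total-count scaling, with cbd-1, which encodes a chitin-binding eggshell protein, at 23915 ± 77.5 against 1796 ± 16.7 CPM (3.73 ± 0.05), cpg-1 at 3.57 ± 0.06 and the chitin synthase chs-1 at 3.42 ± 0.05. Camera gave adjusted p = 6.01e-14, and adjusted p = 0.0522 with an estimated correlation. Among GLD-1 targets (median 2.47, and 0.74 with total-count scaling) were glp-1 (3.44 ± 0.05), egg-1 (3.03 ± 0.06) and oma-2 (2.87 ± 0.06). Their adjusted p was 3.47e-09, and 0.0386 with an estimated correlation. The meiosis list (median 2.06, and 0.33 with total-count scaling, rec-8 2.75 ± 0.07) had adjusted p = 8.97e-11, and 0.0217 with an estimated correlation. The cell cycle list (median 2.31, and 0.58 with total-count scaling, the kinetochore gene knl-1 3.29 ± 0.06) had adjusted p = 2.16e-13, and 0.0377 with an estimated correlation. For germline RNA-binding genes (median 2.38, and 0.65 with total-count scaling, mut-16 3.41 ± 0.06) it was 1.7e-14, and adjusted p = 0.0959 with an estimated correlation. In the MYC IPs the medians of these 5 lists were lower in CEY2 than in the other strains, from −0.72 (cell cycle) to −1.07 (meiosis) relative to CEY4, or −0.24 and −0.58 with total-count scaling. Proteasome subunits were 26 higher and 2 lower of 33 (the same adjusted over the list alone, median 0.85, but −0.88 with total-count scaling, rpn-5 2.04 ± 0.06), with adjusted p = 6.81e-05, and adjusted p = 0.414 with an estimated correlation.

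Collagen, neuron, muscle, intestine and ribosomal protein mRNAs were lower with CEY2. Of 157 collagen genes 128 were lower and 0 higher (129 and 0 adjusted over the list alone, median −1.80, col-122 −2.44 ± 0.07, adjusted p = 2.37e-19, and 0.0379 with an estimated correlation). The CEY2 controls stand apart in this list: its median in the MYC IPs was −0.82 in CEY1 relative to CEY2 and 1.66 in CEY2 relative to CEY4, and FLAG libraries compared without controls gave no call for CEY2 against CEY1 (0.178) or CEY4 (0.0699, ranked the other way). Neuronal genes were 59 lower and 5 higher of 113 (57 and 5 adjusted over the list alone, median −1.09, nlp-24 −2.35 ± 0.12, adjusted p = 1.36e-05, and 0.0214 with an estimated correlation), and their medians in the MYC IPs were −0.44 in CEY1 relative to CEY2 and 0.71 in CEY2 relative to CEY4. Of 79 ribosomal protein genes 66 were lower and 5 higher (67 and 5 adjusted over the list alone, median −1.06), with rps-19 at −2.94 ± 0.07 and rps-13 at −2.94 ± 0.08. Their adjusted p was 6.06e-17, and adjusted p = 0.179 with an estimated correlation. Body wall muscle (25 lower, 6 higher of 35, median −0.76, pat-10 −2.49 ± 0.11, adjusted p = 2.38e-05, and adjusted p = 0.159 with an estimated correlation) and intestine followed. Of 36 intestine genes 25 were lower and 7 higher (median −0.76, acdh-1 −1.68 ± 0.06, adjusted p = 0.000412, and adjusted p = 0.0905 with an estimated correlation), though vit-2 was higher (1.16 ± 0.04, but −0.57 with total-count scaling). Histones were 13 lower and 1 higher of 16 (median −1.04, his-59 −1.52 ± 0.06, adjusted p = 0.000296, and adjusted p = 0.269 with an estimated correlation), and the respiratory chain 26 lower and 9 higher of 45 (median −0.38, adjusted p = 0.00347, and adjusted p = 0.479 with an estimated correlation). For these last 4 lists the counts adjusted over the list alone were the same. With total-count scaling the medians of the 7 lower lists ranged from −2.11 (respiratory chain) to −3.53 (collagens).

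Not called with CEY2 were the pharynx list (20 higher and 23 lower of 74, median −0.28, mean 0.01, adjusted p = 0.748), somatic gonad (3 and 7 of 14, adjusted p = 0.656) and stress genes (9 and 11 of 21, adjusted p = 0.806). Major sperm proteins had 0 higher and 2 lower of 10 (adjusted p = 0.115). Translation factors (22 and 7 of 34, with iff-2 at −2.44 ± 0.09, adjusted p = 0.072) were called as higher without CEY1 MYC replicate 1 (0.0432) or 2 (0.0429). Sperm genes (5 and 14 of 36, adjusted p = 0.0627) were called as lower without CEY2 FLAG replicate 1 (0.0347) or CEY2 MYC replicate 1 (0.0469). Adjusted over the list alone, the counts of these 6 lists differed by at most 1.

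The CEY4 FLAG IP shared several of its top genes with the other strains and held much yolk mRNA. The vitellogenin mRNAs vit-6 (53142 against 8538 CPM, 2.64 ± 0.04) and vit-2 (46941 ± 1221 against 6049 ± 259 CPM, 2.96 ± 0.05) were its 2 most abundant mRNAs. By fold change the order was pqn-20 (4.13 ± 0.08), pqn-54 (3.91 ± 0.18), pqn-41 (3.71 ± 0.07), the kinase wnk-1 (3.62 ± 0.06), pqe-1 (3.60 ± 0.06), spat-3 (3.51 ± 0.06), sumv-1 (3.48 ± 0.07) and pdzd-8 (3.46 ± 0.07). Lowest were the peptide gene nlp-31 (−4.30 ± 0.25), sfxn-5 (−4.01 ± 0.16), math-3 (−3.84 ± 0.17), rpl-39 (−3.82 ± 0.11), ddo-1 (−3.60 ± 0.25), nhr-210 (−3.55 ± 0.24), rpl-36.A (−3.49 ± 0.08) and math-26 (−3.47 ± 0.19). All were called, with adjusted p from 2.11e-37 (vit-2) to 2.04e-16 (ddo-1). In total 4788 genes were higher and 5625 lower. With total-count scaling, which moved the median by −1.41, these were 1405 and 12112.

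The germline RNA-binding, oocyte, cell cycle, meiosis and GLD-1 target lists were higher with CEY4, with the proviso that their medians turned negative with total-count scaling. Germline RNA-binding genes were 31 higher and 0 lower of 34 (median 1.32, and −0.08 with total-count scaling, nos-3 3.07 ± 0.07, adjusted p = 1.33e-13, and adjusted p = 0.0999 with an estimated correlation). Oocyte genes were 32 and 4 of 37 (0.95, and −0.46 with total-count scaling, cbd-1 2.53 ± 0.05, adjusted p = 6.1e-09, and adjusted p = 0.0988 with an estimated correlation). Cell cycle genes were 25 and 2 of 29 (0.86, and −0.56 with total-count scaling, knl-1 2.44 ± 0.06, adjusted p = 5.75e-08, and adjusted p = 0.0735 with an estimated correlation). Meiosis genes were 24 and 2 of 28 (0.82, and −0.60 with total-count scaling, rec-8 2.24 ± 0.06, adjusted p = 6.04e-07, and 0.0375 with an estimated correlation). GLD-1 targets were 13 and 2 of 16 (1.16, and −0.25 with total-count scaling, glp-1 2.04 ± 0.05, adjusted p = 1.88e-05, and adjusted p = 0.0948 with an estimated correlation). The counts of these 5 lists were the same adjusted over the list alone.

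The muscle and pharynx lists were called with CEY4 as well. Body wall muscle was 27 higher and 3 lower of 35 (the same adjusted over the list alone, median 0.73, but −0.69 with total-count scaling), with the myosin unc-54 at 1.92 ± 0.05 and unc-15 at 2.34 ± 0.05. Its adjusted p was 1.38e-06, and adjusted p = 0.116 with an estimated correlation. Pharynx was 50 higher and 9 lower of 74 (50 and 10 adjusted over the list alone, median 1.23, but −0.18 with total-count scaling, the pharyngeal myosin myo-1 2.50 ± 0.06, adjusted p = 2.81e-06, and adjusted p = 0.0948 with an estimated correlation). Lower were ribosomal proteins (54 lower, 18 higher of 79, median −0.70, rps-13 −3.29 ± 0.07 but rps-6 2.27 ± 0.06, adjusted p = 8.6e-08, and adjusted p = 0.414 with an estimated correlation) and collagens (94 lower, 11 higher of 157, median −0.92, col-103 −1.88 ± 0.06, adjusted p = 5.41e-07, and adjusted p = 0.141 with an estimated correlation). The respiratory chain (29 lower, 9 higher of 45, median −0.51) had adjusted p = 0.00259, and adjusted p = 0.468 with an estimated correlation. Sperm genes (20 lower, 6 higher of 36, median −1.14, nspd-2 −3.22 ± 0.22) had adjusted p = 0.0232, and adjusted p = 0.0959 with an estimated correlation. Histones (11 lower, 3 higher of 16, median −0.49, his-2 −2.37 ± 0.10) had adjusted p = 0.0259, which rose to 0.0798 without CEY4 MYC replicate 1, and adjusted p = 0.468 with an estimated correlation. With total-count scaling the medians of these 5 lower lists ranged from −1.90 (histones) to −2.54 (sperm genes). Adjusted over the list alone, their counts differed by at most 1.

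Not called with CEY4 were translation factors (14 higher and 14 lower of 34, median −0.14, mean 0.15, pab-1 2.39 ± 0.05, adjusted p = 0.737), proteasome subunits (12 and 17 of 33, with pbs-5 at −2.21 ± 0.09, adjusted p = 0.516) and intestine (17 and 13 of 36, median 0.10, mean −0.07, adjusted p = 0.368). Neurons (36 and 29 of 113, median 0.13, mean −0.19, ehs-1 2.50 ± 0.07, adjusted p = 0.988), somatic gonad (6 and 4 of 14, adjusted p = 0.552, camera ranked it up at a median of −0.01) and stress genes (8 and 10 of 21, adjusted p = 0.789, ranked up at a median of −0.56) were not called either. Major sperm proteins (0 and 7 of 10, adjusted p = 0.0608) were called as lower without CEY1 MYC replicate 1 (0.0498) or CEY4 MYC replicate 2 (0.0421). Adjusted over the list alone, the counts of these 7 lists differed by at most 2.

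**Figure D3:**
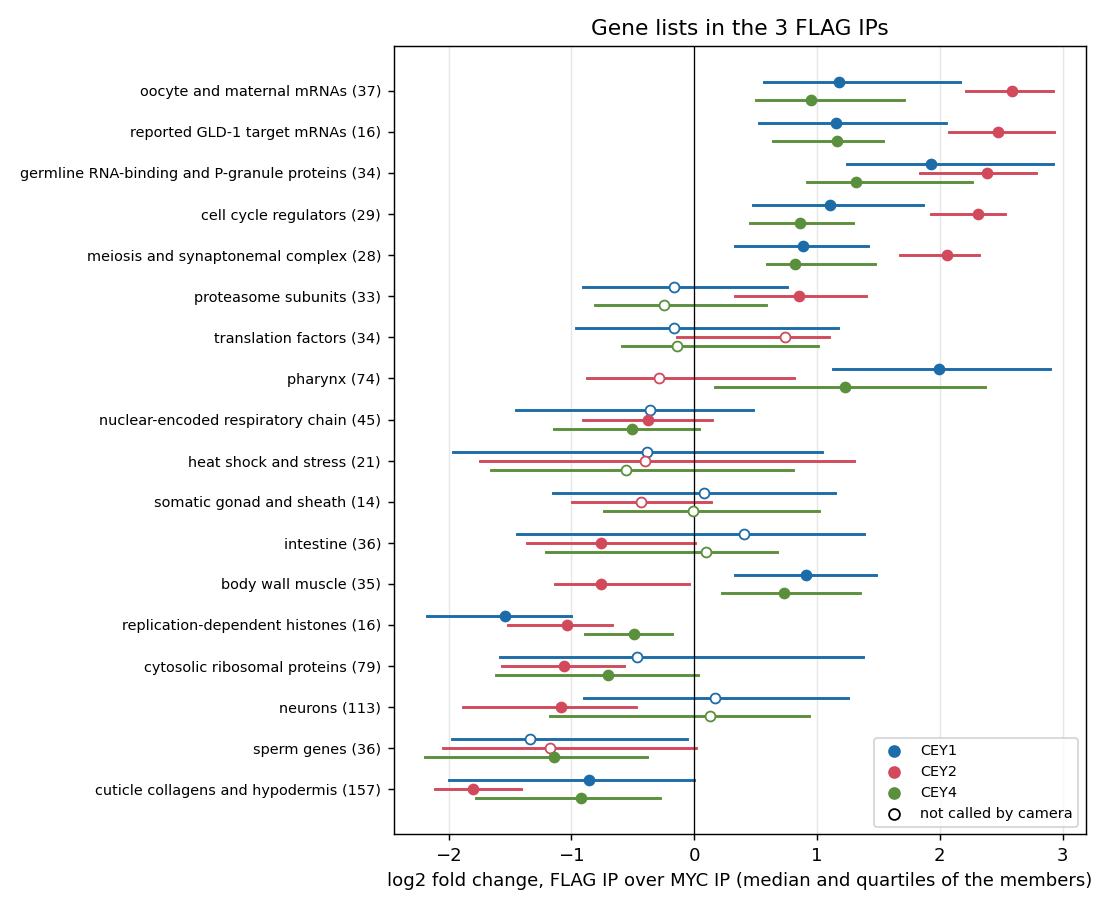
Median (point) and quartiles (line) of the log2 fold change of FLAG over MYC IP for the members of each gene list, by strain; numbers of tested members stand in parentheses, filled points are lists called by camera, and the major sperm proteins are left out. Oocyte genes had medians of 1.18, 2.59 and 0.95 and body wall muscle genes 0.91, −0.76 and 0.73 with CEY1, CEY2 and CEY4; total-count scaling turned the oocyte medians with CEY1 and CEY4 to −0.31 and −0.46 and the muscle medians to −0.58 and −0.69.

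Over the 3 strains together, 4327 genes were higher and 5813 lower in FLAG than in MYC libraries (1047 and 12008 with total-count scaling). That model counts the 2 libraries of a group as separate units. Its p-values therefore do not measure how far the effect of the antibody varies between the 3 strains. Per strain, 3177 genes were called higher and 2346 lower in all 3, where 540 and 659 would be expected if the calls were independent between strains (744 and 8053 with total-count scaling). CEY1 and CEY4 shared 3918 higher genes, CEY2 and CEY4 3735, and CEY1 and CEY2 3505. Called higher in 1 strain alone were 664 genes with CEY1, 1237 with CEY2 and 312 with CEY4, and 2154 genes had opposite calls in at least 2 strains. Across genes, enrichments correlated with r = 0.709 between CEY1 and CEY4, 0.685 between CEY2 and CEY4, and 0.580 between CEY1 and CEY2. Among ribosomal protein genes, 36 of 79 were lower in all 3 strains and 4 higher (58 and 0 with total-count scaling), while 26 were higher with CEY1 and lower with CEY2 (17 with total-count scaling).

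The MYC controls differed between strains, most of all those of CEY2. Between CEY1 and CEY4 controls, 940 genes were higher and 1268 lower in CEY1 (753 lower without CEY1 MYC replicate 2). Against CEY2 controls, 6029 were higher and 2253 lower in CEY1, and 6446 were higher and 2336 lower in CEY4. RLE scaling, which moved these medians by −0.35 and 0.36, gave 3998 and 3628 for CEY1 and 4233 and 3570 for CEY4, and total-count scaling 3370 and 4134 for CEY1 and 3409 and 4192 for CEY4. Germline mRNAs were scarcer in the CEY2 controls: of the meiosis genes 27 of 28 were higher in CEY1 controls (median 0.93, adjusted p = 4.61e-09, and 0.0218 with an estimated correlation) and 28 of 28 in CEY4 controls. Of the sperm genes 25 of 36 were higher in CEY1 than in CEY2 controls (median 1.53, adjusted p = 0.000815, and 0.0437 with an estimated correlation). Collagen mRNAs were more abundant in CEY2 controls, in which 94 of 157 were higher and 26 lower than in CEY4 controls (median 1.66, adjusted p = 2.25e-21, and 0.0352 with an estimated correlation).

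CEY1 and CEY2 were compared to ask whether the proteins recover different mRNAs over their own controls. Here and below, a gene more enriched in 1 strain can still be lower in FLAG than in MYC IPs in both strains. Enrichment was higher with CEY1 for rpl-11.2 (difference of log2 enrichments 4.47 ± 0.08), rps-11 (4.35 ± 0.09), abu-11 (4.33 ± 0.37) and pqn-94 (4.29 ± 0.35). It was higher with CEY2 for cey-2 itself (−4.63 ± 0.08), mrpl-17, of the mitochondrial ribosome (−4.05 ± 0.34), mmab-1 (−3.83 ± 0.22) and the F-box gene fbxa-197 (−3.70 ± 0.29). For cey-1 the difference was 1.92 ± 0.08 and for cey-4 −0.12 ± 0.07 (adjusted p = 0.154, −0.15 and called without CEY1 MYC replicate 1). In total 2803 genes were more enriched with CEY1 and 4773 with CEY2, or 3723 and 3863 with RLE scaling, which moved the median by 0.33. The controls differed for the named genes too. In the MYC IPs, CEY1 minus CEY2, fbxa-197 had 2.32, mmab-1 2.00, cey-2 0.91 and mrpl-17 0.61. The values were 0.13 for rpl-11.2, 0.50 for rps-11, −1.32 for abu-11 and −0.33 for pqn-94. A value opposite in sign to the difference of enrichments enlarges it. The mrpl-17 mRNA was not called with CEY2 itself (0.34 ± 0.19, adjusted p = 0.119 by edgeR).

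Muscle, pharynx, intestine, neuron, collagen and ribosomal protein mRNAs were more enriched with CEY1 than with CEY2. For collagens this means less depleted, as their median was below 0 with both (−0.85 and −1.80). Body wall muscle had 30 of 35 genes higher and 4 lower (the same adjusted over the list alone, median difference 1.75, clik-1 3.47 ± 0.08, adjusted p = 2.43e-16, and 0.0377 with an estimated correlation), and its median in the MYC IPs was 0.18 higher in CEY1. Values in the MYC IPs are medians of the list in the controls, taken in the same order of strains. They rest on the scaling: total-count scaling turned the muscle value to −0.27 and took those that follow to −0.63 (pharynx), 0.11 (intestine), −0.88 (neurons), −1.26 (collagens) and 0.10 (ribosomal proteins). Pharynx had 48 higher and 5 lower of 74 (49 and 5 adjusted over the list alone, median 1.81, adjusted p = 5.65e-14, and 0.0348 with an estimated correlation, and −0.18 in the MYC IPs). Of its 9 genes outside the pqn, abu and phat families, 8 were higher and 1 lower (median 2.08). Intestine had 25 and 3 of 36 (25 and 4 adjusted over the list alone, median 1.13, cpr-1 2.52 ± 0.08, adjusted p = 3.7e-10, and 0.0282 with an estimated correlation, and 0.56 in the MYC IPs), and neurons 47 and 7 of 113 (the same adjusted over the list alone, median 1.05, egl-21 2.25 ± 0.17, adjusted p = 6.29e-07, and 0.0161 with an estimated correlation, and −0.44 in the MYC IPs). Collagens had 75 and 10 of 157 (the same adjusted over the list alone, median 0.93, col-19 3.38 ± 0.08, adjusted p = 2.9e-12, and adjusted p = 0.0722 with an estimated correlation, and −0.82 in the MYC IPs), and the call was lost when FLAG libraries were compared without controls (0.178). Ribosomal proteins had 47 and 22 of 79 (the same adjusted over the list alone, median 0.76, rps-1 3.66 ± 0.08, adjusted p = 1.45e-11, and adjusted p = 0.29 with an estimated correlation, and 0.55 in the MYC IPs).

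The oocyte, GLD-1 target, cell cycle, meiosis and proteasome lists were more enriched with CEY2 than with CEY1. Oocyte genes had 29 of 37 lower and 4 higher with CEY1 (29 and 5 adjusted over the list alone, median −1.46, chs-1 −2.24 ± 0.07, adjusted p = 1.76e-08, and adjusted p = 0.0999 with an estimated correlation), and their median in the MYC IPs was 0.59 higher in CEY1 than in CEY2. GLD-1 targets had 14 lower and 0 higher of 16 (median −1.32, egg-1 −2.66 ± 0.08, adjusted p = 6.54e-08, and adjusted p = 0.0505 with an estimated correlation, and 0.73 in the MYC IPs). Cell cycle genes had 25 and 3 of 29 (median −1.19, rnr-2 −2.13 ± 0.09, adjusted p = 3.78e-08, and adjusted p = 0.0722 with an estimated correlation, and 0.55 in the MYC IPs). Meiosis genes had 25 and 1 of 28 (median −1.12, him-3 −2.83 ± 0.14, adjusted p = 8.31e-08, and 0.0324 with an estimated correlation, and 0.93 in the MYC IPs), and proteasome subunits 27 and 3 of 33 (median −1.02, rpt-6 −2.53 ± 0.11, adjusted p = 3.42e-06, and adjusted p = 0.349 with an estimated correlation, and 0.69 in the MYC IPs). With total-count scaling these 5 medians in the MYC IPs ranged from 0.10 (cell cycle) to 0.49 (meiosis). The calls of the meiosis (0.205) and proteasome (0.112) lists were lost when FLAG libraries were compared without controls. The counts of these last 4 lists were the same adjusted over the list alone. Germline RNA-binding genes were not called (9 higher and 18 lower of 34, median −0.32, and 0.01 with RLE scaling, adjusted p = 0.462), and FLAG libraries compared without controls placed them higher with CEY1 (adjusted p = 0.00709). The other 7 lists were not called in this comparison.

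CEY2 and CEY4 differed in much the same gene groups, though this comparison rests on the same CEY2 libraries as the one before and is not independent of it. Enrichment was higher with CEY2 for trpp-5, of the TRAPP tethering complex (3.05 ± 0.25), pgap-3 (2.98 ± 0.33), tomm-7 (2.96 ± 0.40), oma-2 (2.86 ± 0.08) and cey-2 (2.77 ± 0.08). The chemoreceptor srw-85 was also called (adjusted p = 0.0385), but both CEY4 FLAG libraries held 0 counts of it, so the size of its fitted difference rests on the prior count. Enrichment was higher with CEY4 for pqn-31 (−3.89 ± 0.34), pqn-54 (−3.49 ± 0.25), pqn-36 (−3.22 ± 0.31), pqn-74 (−2.97 ± 0.20) and cey-4 (−2.295 ± 0.07), and cey-1 had −0.50 ± 0.08, but 0.29 between FLAG libraries without controls. Part of these differences lay in the controls. In the MYC IPs, CEY2 minus CEY4, trpp-5 had −1.79, tomm-7 −1.75, pgap-3 −1.12 and cey-2 −0.85. The values were 2.915 for pqn-54, 1.315 for pqn-74 and 1.24 for pqn-36. All of these are opposite in sign to the difference of enrichments and enlarge it. Those of pqn-31 (−0.27) and srw-85 (4.17) had the same sign as the difference. In total 4914 genes were more enriched with CEY2 and 2229 with CEY4, or 3882 and 3233 with RLE scaling and 3953 and 3184 with total-count scaling, which moved the median by −0.33 and −0.32.

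Oocyte genes had 35 of 37 more enriched with CEY2 and 2 with CEY4 (median 1.47, egg-1 2.08 ± 0.08, adjusted p = 1.62e-16, and 0.041 with an estimated correlation), while their median in the MYC IPs was −0.78 in CEY2 relative to CEY4. The cell cycle list had 28 and 0 of 29 (29 and 0 adjusted over the list alone, median 1.38, rnr-2 2.52 ± 0.08, adjusted p = 5.65e-14, and 0.0377 with an estimated correlation, and −0.72 in the MYC IPs), and GLD-1 targets 15 and 0 of 16 (median 1.44, adjusted p = 2.01e-09, and 0.0379 with an estimated correlation, and −0.84 in the MYC IPs). Meiosis genes had 27 and 0 of 28 (median 0.85, spo-11 2.05 ± 0.13, adjusted p = 7.59e-09, and 0.0282 with an estimated correlation, and −1.07 in the MYC IPs). Germline RNA-binding genes had 29 and 1 of 34 (median 0.82, nos-1 2.60 ± 0.14, adjusted p = 2.3e-07, and adjusted p = 0.222 with an estimated correlation, and −0.81 in the MYC IPs). Without controls the meiosis (adjusted p = 0.667) and RNA-binding (adjusted p = 0.81) lists ranked the other way and were not called. Proteasome subunits had 31 and 0 of 33 (median 1.01, pbs-5 2.28 ± 0.14, adjusted p = 3.79e-09, and adjusted p = 0.216 with an estimated correlation, and −0.74 in the MYC IPs). With RLE scaling the median differences of meiosis and RNA-binding genes fell to 0.52 and 0.49, and with total-count scaling the 6 medians in the MYC IPs ranged from −0.58 (meiosis) to −0.24 (cell cycle). Except for the cell cycle list, these counts were the same adjusted over the list alone.

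Muscle mRNAs were more enriched with CEY4 than with CEY2: 30 of 35, against 3 the other way (median −1.67, lev-11 −2.44 ± 0.08, adjusted p = 1.16e-20, and 0.0324 with an estimated correlation, and −0.07 in the MYC IPs). Pharynx had 41 and 11 of 74 (43 and 11 adjusted over the list alone, median −1.26, myo-2 −2.44 ± 0.08, adjusted p = 3.38e-09, and adjusted p = 0.0505 with an estimated correlation, and 0.29 in the MYC IPs). Its 9 genes outside the pqn, abu and phat families had 7 and 0 (median −2.21). Intestine had 24 and 2 of 36 (25 and 2 adjusted over the list alone, median −0.97, vit-6 −1.94 ± 0.06, adjusted p = 2.16e-13, and 0.0214 with an estimated correlation, and −0.45 in the MYC IPs). Collagens had 89 and 4 of 157 (90 and 4 adjusted over the list alone, median −0.94, col-81 −2.01 ± 0.08, adjusted p = 5.33e-19, and 0.0379 with an estimated correlation, and 1.66 in the MYC IPs), but without controls they ranked the other way (adjusted p = 0.0699). Neurons had 46 and 5 of 113 (median −1.03, egl-3 −1.95 ± 0.13, adjusted p = 1.68e-08, and 0.0159 with an estimated correlation, and 0.71 in the MYC IPs), a call lost without controls (0.0683). Ribosomal proteins had 41 and 18 of 79 (41 and 19 adjusted over the list alone, median −0.28, rps-6 −2.09 ± 0.09, adjusted p = 1.69e-07, and adjusted p = 0.415 with an estimated correlation, and −0.23 in the MYC IPs). Histones had 8 and 3 of 16 (median −0.56, adjusted p = 0.00848, and adjusted p = 0.414 with an estimated correlation, and −0.14 in the MYC IPs), a call lost without controls (0.0889). RLE scaling took the median differences of ribosomal proteins and histones to −0.61 and −0.90. Total-count scaling turned the values in the MYC IPs of muscle (0.42), intestine (0.03), ribosomal proteins (0.25) and histones (0.35) positive. For muscle, neurons and histones the counts were the same adjusted over the list alone. The other 6 lists were not called in this comparison.

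CEY1 and CEY4 differed least: 2756 genes were more enriched with CEY1 and 2833 with CEY4. Higher with CEY1 were rps-11 (4.11 ± 0.09), the sperm gene ssp-35 (3.74 ± 0.39), rps-28 (3.67 ± 0.17), rpl-25.2 (3.54 ± 0.09) and cey-1 (1.42 ± 0.08). Higher with CEY4 were epic-2 (−2.96 ± 0.07), the coatomer gene cope-1 (−2.53 ± 0.15), the clathrin adaptor aps-1 (−2.52 ± 0.21), the proton pump gene vha-3 (−2.51 ± 0.15), cey-4 (−2.42 ± 0.07) and cey-2 (−1.86 ± 0.08). Histones, mostly lower in FLAG than in MYC IPs with both proteins, were less depleted with CEY4, 11 of 16 against 2 (the same adjusted over the list alone, median −1.15, his-61 −2.56 ± 0.10, adjusted p = 5.69e-06, and adjusted p = 0.163 with an estimated correlation, and −0.05 in the MYC IPs). Ribosomal proteins were more enriched with CEY1, 45 of 79 against 19 (47 and 19 adjusted over the list alone, median 0.40, adjusted p = 2.73e-08, and adjusted p = 0.402 with an estimated correlation, and 0.32 in the MYC IPs), as were germline RNA-binding genes, 22 of 34 against 5 (23 and 6 adjusted over the list alone, median 0.44, sqd-1 1.85 ± 0.07, adjusted p = 7.09e-06, and adjusted p = 0.294 with an estimated correlation, and −0.11 in the MYC IPs). Oocyte genes had 20 against 11 of 37 (21 and 11 adjusted over the list alone, median 0.27, mex-1 1.57 ± 0.09, adjusted p = 0.0239, and adjusted p = 0.468 with an estimated correlation, and −0.15 in the MYC IPs), a call lost without CEY1 MYC replicate 2 (0.068) or without controls (0.374). Pharynx had 32 against 7 of 74 (33 and 7 adjusted over the list alone, median 0.66, pqn-70 2.24 ± 0.09 but myo-2 −1.53 ± 0.08, adjusted p = 0.000132, and adjusted p = 0.136 with an estimated correlation, and 0.13 in the MYC IPs). Without the pqn, abu and phat families the 9 remaining pharynx genes ranked the other way and were not called (median −0.45, adjusted p = 0.445). The other 14 lists were not called in this comparison.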

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

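Of the tests in this part, the share of counts on chemoreceptor genes and its comparison with genes at the same level, the subtraction of that background, the level of each own mRNA in the controls and the comparison of FLAG libraries alone for lists other than oocyte and muscle genes were chosen after the results were seen. What brings the following results here is a difference between strains in the enrichment of FLAG over MYC, tested as an interaction. The counts were 4773 genes more enriched with CEY2 and 2803 with CEY1, 4914 with CEY2 and 2229 with CEY4, and 2756 with CEY1 and 2833 with CEY4. The imbalance of the first 2 pairs rests on the scaling: they were 3863 and 3723, and 3882 and 3233, with RLE, and 4252 and 4282, and 4026 and 3894, with limma-trend on the deposited values. The own mRNAs differed between strains too: cey-1 by 1.92 (CEY1 minus CEY2) and 1.42 (CEY1 minus CEY4), cey-2 by −4.63 (CEY1 minus CEY2) and 2.77 (CEY2 minus CEY4), and cey-4 by −2.42 (CEY1 minus CEY4) and −2.295 (CEY2 minus CEY4).

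Gene lists differed as follows, in medians of the log2 difference with TMM scaling. For CEY1 minus CEY2 they were 1.81 for pharynx, 1.75 for muscle, 1.13 for intestine, 1.05 for neurons, 0.93 for collagens, 0.76 for ribosomal proteins, −1.46 for oocyte genes, −1.32 for GLD-1 targets, −1.19 for the cell cycle, −1.12 for meiosis and −1.02 for the proteasome. For CEY2 minus CEY4 they were 1.47 for oocyte genes, 1.44 for GLD-1 targets, 1.38 for the cell cycle, 1.01 for the proteasome, 0.85 for meiosis, 0.82 for germline RNA-binding genes, −0.28 for ribosomal proteins, −0.56 for histones, −0.94 for collagens, −0.97 for intestine, −1.03 for neurons, −1.26 for pharynx and −1.67 for muscle; with RLE scaling, meiosis (0.52), germline RNA-binding genes (0.49), ribosomal proteins (−0.61) and histones (−0.90) moved by over 1.5 times. For CEY1 minus CEY4 they were 0.66 for pharynx, 0.44 for germline RNA-binding genes, 0.40 for ribosomal proteins, 0.27 for oocyte genes and −1.15 for histones. No list was called for CEY1 minus CEY4 with an estimated correlation. The oocyte call was lost in FLAG libraries compared without controls. Without its pqn, abu and phat families the pharynx list ranked the other way and was not called (median −0.45).

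The first pattern weighed concerns CEY2 against both CEY1 and CEY4. The oocyte, GLD-1 target, cell cycle and meiosis lists were higher with CEY2, and the muscle, pharynx, intestine, collagen and neuron lists lower. RNA-binding genes were higher than with CEY4 but not called against CEY1, and sperm, somatic gonad and stress genes were not called. With an estimated correlation the oocyte, GLD-1 target, cell cycle and collagen lists were no longer called against CEY1. The same held for the pharynx list and RNA-binding genes against CEY4. The CEY2 controls stand apart from the others (r = 0.916 and 0.921 with the CEY1 and CEY4 controls, which correlate at 0.968 with each other), but FLAG libraries compared alone kept at least 0.682 of the gap between the oocyte and muscle medians (3.21 to 2.39 against CEY1, 3.14 to 2.14 against CEY4), which argues against the controls as the whole of that gap. Removing the trend with abundance kept at least 0.999 of the gap, which argues against that trend as well. For the other lists the answer was mixed. The controls stay open for 6 of 15 called differences, which were lost or turned in FLAG libraries alone. These were meiosis (0.205) and collagens (0.178) against CEY1, and meiosis (0.667), germline RNA-binding genes (0.81), collagens (0.0699) and neurons (0.0683) against CEY4. RNA-binding genes, not called against CEY1, were then higher with CEY1 (0.00709). The other 9 kept their call by camera at the preset correlation, which argues against the controls as the whole of those differences. Against CEY1 and CEY4 they were intestine (9.3e-12, 1.24e-13), pharynx (1.59e-09, 0.00953), cell cycle (0.000388, 1.04e-07) and GLD-1 targets (0.00119, 0.000166). Neurons were kept against CEY1 alone (0.00458). A difference between strains in where or when the tagged protein is made, which the cey-1, cey-2 and dpy-30 promoters could bring, and a difference in the mRNAs that each protein binds stay open as biological explanations, untested, as does binding after lysis.

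The second pattern is that scarcer mRNAs tended to be lower in the FLAG libraries, with Spearman's rho of 0.440, 0.620 and 0.577 (CEY1, CEY2, CEY4) across genes between the log2 fold change and the control level in the other strains. The median log2 ratio (total-count scaling, 0.1 CPM added) was −0.37, 0.09 and −0.24 for genes over 100 CPM, −1.42, −0.92 and −1.32 at 10 to 100 CPM, and −2.04, −2.53 and −2.05 at 1 to 10 CPM, and −0.81, −1.36 and −1.43 under 1 CPM, where the added 0.1 CPM pulls the ratio toward 0, so that these values do not show whether the trend goes on. After the FLAG libraries were thinned to MYC depth, rho was 0.448, 0.620 and 0.534, a change of at most 0.0430 in size. The filter was rerun on the thinned counts and left 12611 genes, so rho before and after covers different genes. Among the genes left the trend remained at equal depth, which argues against depth as the whole of the trend there. For the scarcer genes that the filter removed, thinning decides nothing. For an evenly spread background in the MYC libraries, chemoreceptor genes, which whole adults barely express, held at least 9.54 times the share of counts in MYC that they held in FLAG libraries, and 3.16, 4.27 and 3.77 times as large a ratio as other genes at the same control level, so it stays open as a part of the trend, as does the origin of these mRNAs in neurons. That share was first computed on a symbol pattern that by mistake took in unrelated genes (1345 genes; ratios of 1.06, 0.726 and 0.943), and was corrected to the serpentine receptor families (1294 genes) after this had been seen. Subtracting this background removed at most 0.0867 of the gap between genes at 1 to 10 CPM and genes over 100 CPM. That follows from its size in the MYC libraries (0.125, 0.222 and 0.232 CPM for CEY1, CEY2 and CEY4), so it is not a separate test. An even background of that size is too small to be the whole of the trend there. Under 1 CPM, where the subtracted background is of the size of the values, this subtraction decides nothing. Gene length, which was not tested, and a preference of the proteins for abundant mRNAs stay open.

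The third pattern is that each tagged protein's own mRNA was most enriched in its own FLAG IP. More of the mRNA in the lysate from the added gene copy stays open, because none of the libraries is from the lysate. The log2 excess in the own MYC libraries was at most 0.286 of the excess of enrichment. That ratio does not decide the question, because the enrichment is already taken relative to the same MYC libraries. The anti-FLAG antibody could also hold the nascent tagged peptide on ribosomes that translate its mRNA, and binding of each protein to its own mRNA is the biological alternative; neither was tested.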

How the results depend on the processing

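Total-count scaling, thinning, FLAG libraries compared directly and the reduced pharynx list were chosen after the data were seen; all other settings were chosen before. The directions of FLAG over MYC rest on the scaling: between 1405 and 2013 genes per strain were higher with total-count scaling. Scarce mRNAs are limited by depth, since 1 CPM before TMM scaling is 3.35 counts in the smallest library. A library left alone in its group is assumed to vary like the others. Scaling on mitochondrially encoded mRNAs was not run, as the table holds none, and fits to the libraries compared alone do not apply to the comparison over all strains.

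A result is counted as unchanged if it kept direction and side of the threshold, or if neither setting called it, whatever its direction. Of 254 gene results, 252 stayed unchanged with RLE, 252 with DESeq2, 251 without a filter, 252 with only the libraries compared, 248 with thinning, 237 with limma-trend and 237 with total-count scaling. With the 10 CPM filter 239 of the 249 still tested did. With each library left out, 3032 of 3048 did, as did 1354 of 1368 list results. Counts of calls are compared by size: 311 of 312 stayed within 1.5 times the count with all libraries, and the genes lower in CEY1 than CEY4 controls ranged from 753 to 1512. The labels do not say whether the replicate numbers pair the libraries. Replicate differences of FLAG and MYC libraries of equal number correlated at −0.0631, −0.0324 and −0.0567 across genes. With 2 libraries per group this does not decide whether they are paired. With the replicate block all 254 gene results stayed unchanged in the same sense, and all 26 counts stayed within 1.5 times, the largest move being to 3915 higher and 5167 lower over all strains. The respiratory chain with CEY1 (0.0431) and sperm genes with CEY2 (0.0495) passed the threshold.

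With limma-trend on the deposited log2 values, genes higher and lower in FLAG were 1635 and 10093 (CEY1), 2049 and 10558 (CEY2), 1350 and 10834 (CEY4), and 1056 and 11653 (all strains). With total-count scaling they were 1647 and 10849, 2013 and 10892, 1405 and 12112, and 1047 and 12008. Total-count scaling moved the median of all genes by −1.49, −1.71 and −1.41 (CEY1, CEY2, CEY4), and limma-trend, where 8 is added, by −0.59, −0.54 and −0.51. The following turned negative (limma-trend, then total-count scaling). With CEY1: cey-4 (−0.77, −0.77), lin-28 (−0.82, −0.85) and unc-119 (−0.58, −0.83). With CEY2: vit-2 (−0.57, −0.57), cey-1 (−0.31, −0.31), cey-3 (−0.68, −0.68), cey-4 (−0.88, −0.89), lin-28 (−0.50, −0.55), tbb-2 (−0.62, −0.62), unc-119 (−0.82, −1.20) and dpy-30 (−0.75, −0.78). With CEY4: cey-2 (−1.16, −1.17), lin-28 (−1.11, −1.18) and tbb-2 (−1.08, −1.08). The difference of srw-85 (CEY2 minus CEY4), 3.65 ± 1.47 with the prior count, was −2.79 with limma-trend.

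The 10 CPM filter, which tests fewer genes, gave 3163 higher with CEY4, 2716 higher and 3170 lower over all strains, 3549 higher in CEY1 than CEY2 controls and 3849 lower in CEY2 than CEY4 controls. It turned cey-4 with CEY2 (−0.0284) and, with CEY4, cey-2 (−0.26), lin-28 (−0.27) and tbb-2 (−0.17); thinning turned cey-2 with CEY4 (−0.0460). The cey-4 difference of CEY1 minus CEY2, −0.12 and not called, was 0.21 with RLE, 0.21 with DESeq2 and 0.30 with the filter. The causes were not tested.

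With limma-trend 4282 genes were more enriched with CEY1 than CEY2 and 3894 with CEY4 than CEY2; FLAG libraries compared directly gave 4539 and 4151, and turned cey-1 for CEY2 minus CEY4 (0.29). In CEY1 against CEY2 controls, genes higher were 3998 (RLE), 3162 (only these libraries), 3507 (DESeq2) and 3370 (total-count scaling), and genes lower 3628 (RLE), 5131 (limma-trend) and 4134 (total-count scaling). In CEY1 against CEY4 controls, 586 were higher and 496 lower with only these libraries, and 603 and 806 with DESeq2. In CEY2 against CEY4 controls, genes higher were 3570 (RLE), 3533 (only these libraries), 4830 (limma-trend) and 4192 (total-count scaling), and genes lower 4233, 3421, 3997 and 3409 in the same order, and 3690 with DESeq2. The cause was not tested.

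An estimated correlation called 0, 5 and 1 lists (CEY1, CEY2, CEY4; 9, 13 and 12 with the preset one), and for differences 5 (CEY1 minus CEY2), 0 (CEY1 minus CEY4) and 8 (CEY2 minus CEY4; 11, 5 and 13 with the preset one). How far correlation within the lists accounts for the lost calls was not tested. The rotation test fry, which asks about the list's own genes, called 17 lists with CEY1. It gave the opposite direction for pharynx (4.7e-05), somatic gonad (1.27e-05) and stress genes (0.00957) with CEY2, neurons with CEY4 (5.3e-05) and sperm genes for CEY2 minus CEY4 (0.0109), none of them called by camera. FLAG libraries compared directly turned germline RNA-binding genes (0.00709 for CEY1 minus CEY2, 0.81 for CEY2 minus CEY4), meiosis (0.667) and collagens (0.0699, both CEY2 minus CEY4). For CEY1 minus CEY2 they lost proteasome (0.112), meiosis (0.205) and collagens (0.178) and gained the respiratory chain (0.0164), sperm genes (0.000192) and histones (0.0137). For CEY2 minus CEY4 they lost histones (0.0889) and neurons (0.0683) and gained the respiratory chain (0.00635) and sperm genes (0.00079), and for CEY1 minus CEY4 they lost oocyte genes (0.374) and gained collagens (4.17e-06). RLE gained the respiratory chain with CEY1 (0.0479) and for CEY2 minus CEY4 (0.0397). The reduced pharynx list turned for CEY1 minus CEY4 (0.445). The cause was not tested.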

Other observations

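The gene families in this part, 80 groups of genes that share a symbol prefix, and their tests were chosen after the data were examined. None of them was called with an estimated correlation (lowest adjusted p = 0.0903 over all families and comparisons). Most nucleoporin genes (npp) were higher with all 3 proteins: of 26, 22 were higher and 3 lower with CEY1, 25 and 0 with CEY2, and 21 and 0 with CEY4. Their medians were 1.49, 2.25 and 1.33, but 0.00, 0.52 and −0.08 with total-count scaling. Camera gave adjusted p = 2.09e-06, 5.42e-10 and 2.48e-08 over all families and comparisons, and adjusted p = 0.169, 0.121 and 0.152 with an estimated correlation. SET-domain genes (set) were 23 higher and 2 lower with CEY1, 24 and 3 with CEY2, and 20 and 3 with CEY4 of 29, with medians of 1.07, 1.85 and 0.96, but −0.42, 0.12 and −0.46 with total-count scaling (adjusted p = 3.65e-05, 6.1e-05 and 8.25e-05, and adjusted p = 0.167, 0.169 and 0.169 with an estimated correlation). Genes of vacuolar sorting (vps) were 20 higher and 7 lower with CEY1, 30 and 0 with CEY2, and 21 and 5 with CEY4 of 31, with medians of 0.51, 1.56 and 0.72, but −0.98, −0.17 and −0.69 with total-count scaling (adjusted p = 0.0116, 7.88e-08 and 0.000355, and adjusted p = 0.169, 0.0903 and 0.121 with an estimated correlation).

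Transthyretin-related genes (ttr) had 42, 42 and 45 of 55 lower with CEY1, CEY2 and CEY4 and 1 higher with each, with medians of −2.53, −2.21 and −2.24, and −3.998, −3.92 and −3.65 with total-count scaling (adjusted p = 6e-06, 8.95e-06 and 4.07e-06, and adjusted p = 0.0903 with an estimated correlation). Glucuronosyltransferases (ugt) had 40, 48 and 45 of 62 lower and 1, 1 and 3 higher (medians −1.37, −1.75 and −1.29, and −2.86, −3.47 and −2.70 with total-count scaling, adjusted p = 4.41e-05, 6.61e-07 and 6.48e-05, and adjusted p = 0.121, 0.0935 and 0.121 with an estimated correlation). Glutathione S-transferases (gst) had 30, 22 and 27 of 39 lower and 0 higher (medians −2.301, −1.56 and −1.41, and −3.76, −3.28 and −2.82 with total-count scaling, adjusted p = 0.000238, 0.000685 and 0.000525, and adjusted p = 0.152, 0.16 and 0.152 with an estimated correlation). The median control levels of the ttr, ugt and gst genes were 2.101, 4.44 and 1.71 CPM. Whether the trend with control level contributes to the calls of these families, of the npp, set and vps genes, or of the gene lists within a strain was not tested.

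Over the 3 strains, 10140 genes were called between the 6 FLAG and the 6 MYC libraries. Among 100 splits of the 12 libraries into 6 and 6, the real one included, 1 reached that number, and the highest other split gave 3878. The splits moved single libraries and not whole groups, so the closely similar replicates of a group could fall on opposite sides. Such splits raise the spread and give few calls, with a median of 0 over the other splits. This count therefore does not decide whether the difference arose by chance.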
